A study of Mus musculus with 30 samples.

How the data were processed

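RNA was measured in 30 libraries of naive mouse embryonic stem cells of a C57BL/6J x 129 background, grown with serum, LIF, a MEK inhibitor and a GSK3 inhibitor, per the labels' protocols. Per the same protocols, the libraries were made with a QuantSeq kit, which reads a tag near the 3' end of each transcript, and were sequenced from a single end. The libraries formed 10 groups of 3. Kmt2c-KO cells, whose label also gives floxed Kmt2d alleles, and Kmt2c/Kmt2d double-KO cells carried GRHL2-ERT and received ethanol or tamoxifen for 8 h or 16 h. Kmt2c-KO cells without GRHL2-ERT received tamoxifen for 8 h or 16 h. The labels number the replicates without saying whether they were separate cultures, so every p measured only the spread between these libraries.

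The deposited table held log2 values for 12428 genes in 30 library columns, with 10 columns of group means and 6 columns of differences. The submitters' processing notes name Salmon, DESeq2 1.34.0 and the mm10 build, without the step each was used for, and further settings were not given in the sources used here. Each deposited value was the log2 of CPM (counts scaled to the same total in each library) plus a common offset of 0.124871, and each library's CPM were shares of the total over the genes of the table. The deposited means and differences matched the library columns to within 4.7e-08. Every listed gene had at least 1 CPM in at least 6 libraries. The deposited column names shorten the line names, and the columns of Kmt2c-KO cells with and without GRHL2-ERT were told apart by the treatments that the labels give for each line.

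Reads per library were recovered from the spacing of the lowest values. Between 94.5% and 97.6% of the low values were whole numbers of reads within 0.05 reads. The recovered depth ran from 8.86 to 22.0 M reads over the table's genes, with a median of 16.2 M reads. A floor of 3 reads in 1 library stood for 0.136 to 0.339 CPM. The labels name no molecular identifiers, so these floors covered counting error only. Genes were placed on mm10 with GENCODE mouse release 21, in which 11969 symbols (96.3%) were found.

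Values were returned to CPM and tested as log2(CPM + 1) with limma 3.58.1 in R 4.3.3, with a mean per group over all 30 libraries, a trend of variance with level, robust moderation and 20 residual degrees of freedom. The 12414 genes with a group mean of at least 1 CPM in at least 1 group were tested, and 14 were removed. A gene was called at a Benjamini-Hochberg adjusted p under 0.05 over the tested genes, two-sided, in each of 14 contrasts. Log2 fold changes are given with the SE of the model and CPM with the SD over libraries. The count models chosen before the data were examined were not run because the values are log2, and the limma test fixed for that case took their place. The contrasts, the gene lists, the rule for named genes and the alternatives named first below were also fixed before the data were examined.

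Genes were named by rule. A named gene had an adjusted p under 0.05, a mean of at least 1 CPM, groups that did not overlap (for a difference of responses, in at least 1 line) and a gene symbol other than a predicted or clone name. Chance separates 3 libraries from 3 others for 10% of unchanged genes. The rule took the 10 largest increases and 6 largest decreases for tamoxifen contrasts, 10 reductions and 6 gains for differences between lines, 8 in each direction for the lines in ethanol, and 4 in each direction elsewhere. It added up to 4 list members with the smallest adjusted p, and always Grhl2, Kmt2c and Kmt2d. Genes named outside the rule are marked as such, and 1 gene that the rule names is not reported here.

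Each of 22 gene lists was tested per contrast with camera at a preset correlation of 0.01, with camera at an estimated correlation and with fry, all in limma, and p was adjusted over the lists of a contrast. The mitochondrial list had 0 measured members and gave no result. To compare lines, genes called with an average log2 fold change of at least 1 over both lines at one time were measured at the other time. For repressed genes an average of at most -1 gave 4 genes, so the average of at most -0.5 that the plan held for that case was used. Expected overlaps assumed independent genes, and for contrasts that share libraries the overlap and the covariance of log2 fold changes were also taken from 20 simulations of unchanged groups.

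The alternatives fixed then were pseudocounts of 0.1 and 5, no filter, a log2 fold change of at least 1 with the same adjusted p, the libraries of 1 contrast alone, a replicate block over all libraries or within each line and time, leaving out each library, other choices of induced genes, and a slope in place of their median. For the medians over induced and repressed genes median-of-ratios scaling was fixed then as well. A count model (edgeR) on recovered reads was also fixed then as an added alternative, and was not run. Added after the data were seen were median-of-ratios scaling for the other results, the deposited log2 values, voom weights on recovered reads, array weights, the level of Rn45s as a covariate, and a fit without 3 libraries that stood apart. Those 3 were the double-KO tamoxifen libraries of replicate 2 at 8 h and at 16 h, and the 16 h library of replicate 1 without GRHL2-ERT. The test was tried on simulated data of 12414 genes with 200 changed genes in 5 runs. With a spread pooled over groups it made 3.84% to 5.14% false calls, and it recovered 77.0% to 78.8% of changes of log2 1 in the tamoxifen contrasts, and 51.2% at 8 h and 54.8% at 16 h in the differences between lines. With each group's own spread, false calls made up 67.7% for tamoxifen in double-KO cells at 8 h and 37.5% for the difference between lines at 8 h. Noise was drawn for each gene alone, so these shares need not hold for the real calls. Figures were drawn with Python 3.11.15, matplotlib 3.10.9, pandas 2.3.3 and numpy 2.4.6. The deposited differences served as a check of the columns and were otherwise not used here.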

Results

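RNA levels were measured by 3' tag sequencing in naive mouse embryonic stem cells that lack KMT2C or both KMT2C and KMT2D, a pair of histone methyltransferases that act at enhancers. The cells carried GRHL2-ERT, an epithelial transcription factor fused to an estrogen receptor domain that tamoxifen brings into the nucleus. GRHL2-ERT Kmt2c-KO cells and GRHL2-ERT double-KO cells had 3 libraries each with ethanol and with tamoxifen, at 8 h and at 16 h. Kmt2c-KO cells without GRHL2-ERT had 3 tamoxifen libraries at each time. Recovered depth ran from 8.86 M reads in the double-KO tamoxifen library of replicate 2 at 8 h to 22.0 M reads in the double-KO ethanol library of replicate 2 at 8 h. The first principal component of all genes (45.6% of variance) separated double-KO from Kmt2c-KO libraries, with and without GRHL2-ERT alike, and the next (27.6%) separated 8 h from 16 h. The labels name no preparation batches.

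Tags of Grhl2 (mm10 chromosome 15, 37233036 to 37363569) were scarce without the transgene, at 2.66 ± 0.831 CPM (SD, n = 3) at 8 h and 1.78 ± 0.617 CPM at 16 h. In GRHL2-ERT Kmt2c-KO cells at 8 h they reached 178 ± 28.3 CPM in ethanol and 170 ± 16.4 CPM in tamoxifen. In GRHL2-ERT double-KO cells at 8 h they reached 41.2 ± 10.1 CPM in ethanol and 78.3 ± 40.8 CPM in tamoxifen. At 16 h Kmt2c-KO cells had 77.6 ± 11.1 CPM in ethanol and 77.5 ± 11.5 CPM in tamoxifen, and double-KO cells had 52.5 ± 7.89 CPM and 57.5 ± 11.5 CPM. The labels say that clones were chosen for similar GRHL2 expression. Tags of Grhl2 RNA were 1.35 to 4.32 times higher in the Kmt2c-KO line, and protein, which may differ from RNA tags, was not measured here. Esr1, the estrogen receptor gene, had 53.6 ± 11.3 CPM in Kmt2c-KO and 7.91 ± 7.44 CPM in double-KO cells with tamoxifen at 8 h, against 3.39 ± 0.397 CPM without GRHL2-ERT. These double-KO libraries ran from 1.02 CPM in replicate 2 to 15.8 CPM in replicate 3. At 16 h with tamoxifen Esr1 had 61.2 ± 2.60 CPM in Kmt2c-KO and 30.6 ± 1.93 CPM in double-KO cells, against 6.78 ± 1.51 CPM without GRHL2-ERT. In ethanol Grhl2 was lower in double-KO than in Kmt2c-KO cells at 8 h (log2 fold change -2.10 ± 0.25 SE; limma adjusted p = 1.5e-07) and did not pass at 16 h (-0.56 ± 0.25; adjusted p = 0.062). With median-of-ratios scaling, which takes out a shift of all genes between these lines, it was lower at 16 h as well (-0.92 ± 0.27; adjusted p = 7.1e-03).

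Kmt2c (chromosome 5, 25271798 to 25498783) had 19.6 ± 3.93 CPM in Kmt2c-KO and 29.5 ± 3.22 CPM in double-KO cells with ethanol at 8 h. With tamoxifen at 8 h Kmt2c had 26.8 ± 5.56 CPM and 23.5 ± 3.32 CPM, and 15.7 ± 2.44 CPM without GRHL2-ERT. At 16 h Kmt2c had 11.2 ± 0.839 CPM and 18.9 ± 0.396 CPM with ethanol, 11.8 ± 0.995 CPM and 21.6 ± 1.53 CPM with tamoxifen, and 11.2 ± 1.73 CPM without GRHL2-ERT. Kmt2d (chromosome 15, 98831669 to 98871204) had 18.2 ± 4.49 CPM in Kmt2c-KO and 9.70 ± 3.94 CPM in double-KO cells with ethanol at 8 h, 11.5 ± 2.36 CPM and 7.29 ± 0.855 CPM with tamoxifen, and 10.0 ± 3.14 CPM without GRHL2-ERT. At 16 h Kmt2d had 8.79 ± 0.291 CPM and 7.64 ± 0.889 CPM with ethanol, 8.76 ± 1.73 CPM and 9.20 ± 1.87 CPM with tamoxifen, and 6.91 ± 0.788 CPM without GRHL2-ERT. In ethanol at 8 h Kmt2c was higher (0.58 ± 0.16; limma adjusted p = 4.0e-03) and Kmt2d lower (-0.89 ± 0.23; adjusted p = 2.5e-03) in double-KO cells. At 16 h Kmt2c was higher (0.70 ± 0.16; adjusted p = 6.4e-04) and Kmt2d did not pass (-0.18 ± 0.23; adjusted p = 0.53). With median-of-ratios scaling Kmt2c no longer passed at 8 h (0.28 ± 0.16; adjusted p = 0.16) or at 16 h (0.36 ± 0.16; adjusted p = 0.069), and Kmt2d was lower at 8 h (-1.18 ± 0.23; adjusted p = 1.1e-04) and did not pass at 16 h (-0.51 ± 0.23; adjusted p = 0.069). The sources do not give the deleted part of either gene, and a tag at the 3' end outside that part checks neither knockout.

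**Figure D1:**
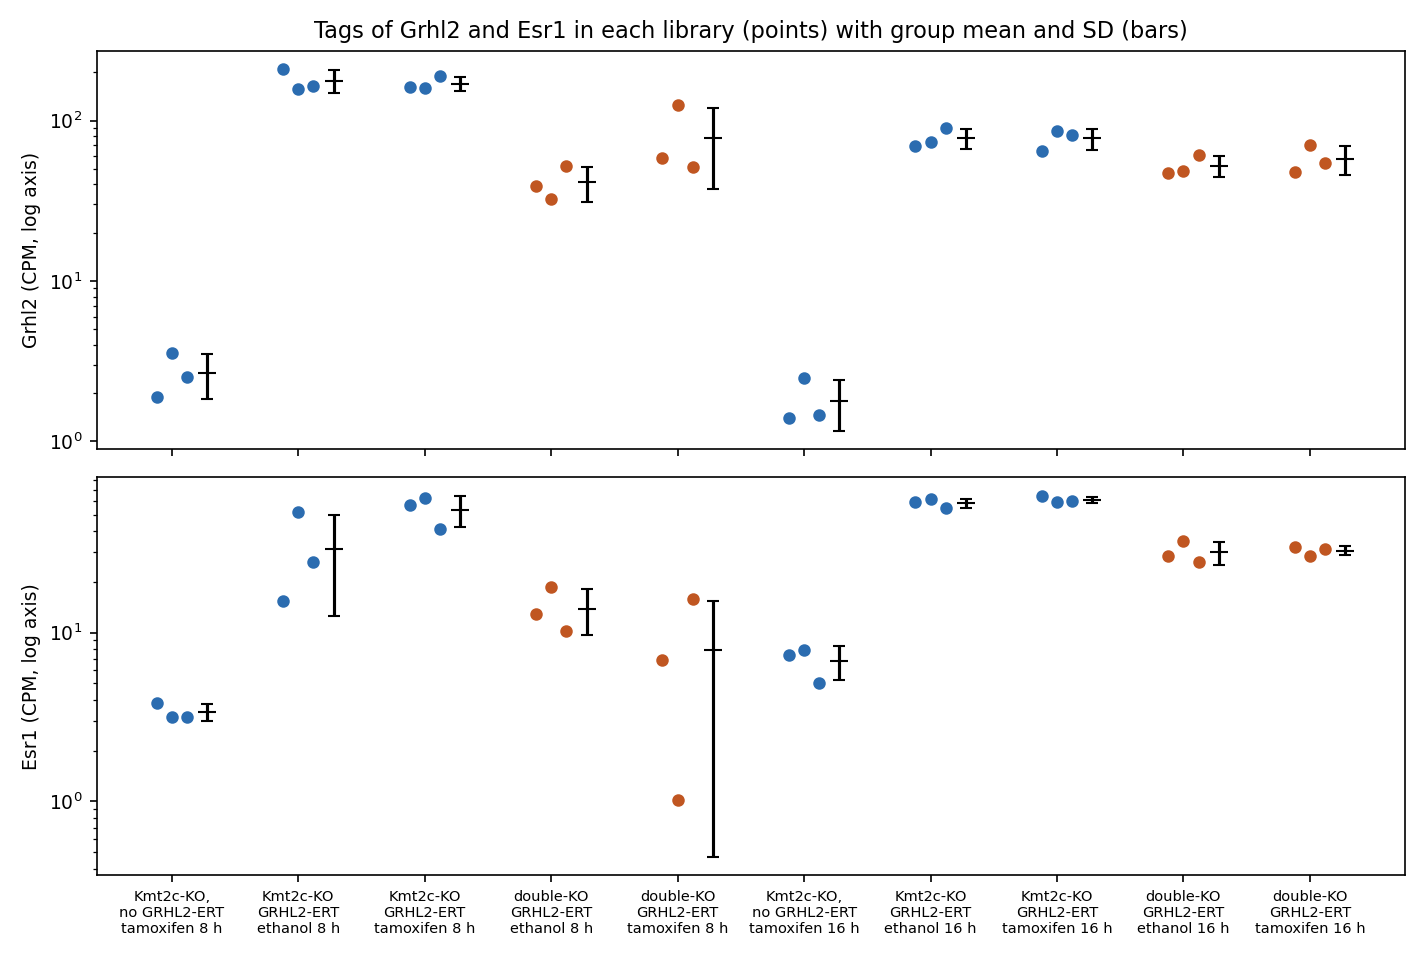
Grhl2 and Esr1 levels in CPM on a log axis for each of 30 libraries, by line, treatment and time, with the mean and SD of each group of 3. Grhl2 lay between 41.2 and 178 CPM in group means with GRHL2-ERT and at 1.78 and 2.66 CPM without it.

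Tamoxifen for 8 h in GRHL2-ERT Kmt2c-KO cells, which asks what nuclear GRHL2 changes in cells that keep floxed Kmt2d, raised genes of epithelial cells. Aldh3b2, an aldehyde dehydrogenase gene (chromosome 19, 3972328 to 3981646), was listed at 0 in all 3 ethanol libraries and reached 9.40 ± 0.936 CPM (SD, n = 3). That level was at least 46.6-fold higher, against a floor of 3 reads per library averaged over the group. Wnt7b, a Wnt ligand gene (chromosome 15, 85535437 to 85582473), rose from 1.30 ± 0.215 to 20.8 ± 3.52 CPM, a log2 fold change of 3.24 ± 0.24 (SE; limma adjusted p = 4.3e-10). Esrp1, an epithelial splicing regulator (chromosome 4, 11331933 to 11386783), rose from 5.85 ± 1.70 to 27.7 ± 1.05 CPM (2.10 ± 0.27; adjusted p = 7.1e-06). Other named increases were Bnipl (3.10 ± 0.28), Tmem54 (3.08 ± 0.25), Pea15a (2.51 ± 0.20), Sord (2.36 ± 0.19), Acsl5 (2.33 ± 0.21) and the cornified envelope gene Ppl (2.22 ± 0.26). Of 40 measured GRHL2 epithelial targets, 18 rose, 0 fell and 22 did not pass, and 26 rose adjusted over the list alone. They included Epcam (0.77 ± 0.15; adjusted p = 1.4e-03), the claudin genes Cldn4 (0.75 ± 0.13; adjusted p = 6.8e-04) and Cldn6 (1.82), and cingulin, Cgn (2.11 ± 0.35; adjusted p = 3.7e-04). The list's median was 0.74 (camera adjusted p = 7.2e-19, and adjusted p = 0.00021 with an estimated correlation).

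Other junction and lineage lists also moved in these cells at 8 h. Of 20 tight junction genes, which share 9 symbols with the GRHL2 list, 6 rose (Cgn, Cldn4, Cldn6, Cldn7, Crb3 and Marveld3) and 14 did not pass, and 10 rose and 1 fell adjusted over the list alone. Of 16 desmosome and adherens junction genes 2 rose (Perp and Ppl), and 6 adjusted over the list alone. Of 17 trophoblast genes 6 rose (Dlx3, Esx1, Gata2, Id2, Krt8 and Krt18), with the same 6 adjusted over the list alone. Of 26 cholesterol synthesis and SREBP genes 6 rose (Cyp51, Fdps, Msmo1, Sc5d, Stard4 and Tm7sf2), and 8 adjusted over the list alone. Of 9 keratin genes 2 rose (Krt8 and Krt18), also adjusted over the list alone, with a camera adjusted p = 0.034 and adjusted p = 0.10 with an estimated correlation. The other 4 of these calls held, with an adjusted p = 0.011, 0.018, 0.033 and 0.017 with an estimated correlation.

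Genes of pluripotent and mesenchymal cells fell in the same comparison. Tcl1, a co-activator of AKT kinase expressed in naive cells, fell from 18.4 ± 2.97 to 5.05 ± 1.12 CPM (-1.69 ± 0.18; limma adjusted p = 3.4e-07). Zeb1, a repressor of epithelial genes, fell to 8.02 ± 2.55 CPM in tamoxifen (-1.22 ± 0.17; adjusted p = 3.4e-05). Utf1 fell from 56.5 ± 3.97 to 24.1 ± 1.33 CPM (-1.19 ± 0.13; adjusted p = 2.2e-07), and Lefty2, a Nodal antagonist gene, fell by 1.05 ± 0.11. Rab26, Smarcd3, Rassf4, Runx1t1 and Myo1f had the next largest falls, from -1.53 ± 0.34 to -1.35 ± 0.23. Of 22 naive pluripotency genes 5 fell (Klf4, Klf5, Sox2, Tcl1 and Zfp42), and 6 adjusted over the list alone (adjusted p = 0.025 with an estimated correlation). Of 19 formative and primed genes 5 fell (Dnmt3a, Dnmt3l, Sall2, Utf1 and Zic2) and Otx2 rose, with 8 and 2 adjusted over the list alone (adjusted p = 0.033 with an estimated correlation). Of 15 mesenchymal genes 3 fell (Cdh2, Sparc and Zeb1), and 4 adjusted over the list alone (adjusted p = 0.033 with an estimated correlation). Over all genes 362 rose and 253 fell, of which 154 and 50 changed by at least 1 on the log2 scale. The total of 615 was 320 without the tamoxifen library of replicate 2, 1116 with array weights, and 1380 without 3 libraries that stood apart. Those 3 belong to other groups, so leaving them out changed the spread shared by all groups and not the means compared here. The ribosomal RNA gene Rn45s, a sign of how the RNA was selected, fell by 0.73 ± 0.21 (adjusted p = 3.9e-02) beside these gene groups, and took 7.40% of reads in the ethanol library of replicate 3. With its level as a covariate 445 genes were called, of which 273 were among the 615.

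After 16 h, tamoxifen raised 36 genes and lowered 1 in GRHL2-ERT Kmt2c-KO cells. Tmem54, a membrane protein gene (chromosome 4, 129105548 to 129111626), rose from 0.111 ± 0.0992 to 5.79 ± 1.37 CPM (2.60 ± 0.25; limma adjusted p = 4.1e-07). Acsl5, an acyl-CoA synthetase gene, rose by 1.83 (adjusted p = 1.4e-05). Bnipl (1.94), Wnt7b (1.65), Pea15a (1.62), Hsbp1l1 (1.55), Esrp1 (1.53) and Ppl (1.45) rose as well. Plac9a was listed at 0 in all libraries at 8 h, and at 16 h had 1.32 ± 2.29 CPM in ethanol, 7.31 ± 1.19 CPM in tamoxifen and 9.19 ± 3.93 CPM without GRHL2-ERT. The 36 increases included 33 that also rose at 8 h, where independence gives 1.05, and these contrasts share no libraries. The 1 decrease was Calcoco2, a selective autophagy receptor gene (-0.39 ± 0.09; adjusted p = 3.6e-02). Of 40 GRHL2 targets 5 rose, among them Cldn4, Cldn6, Esrp1 and Ppl, and 12 rose adjusted over the list alone, with a median of 0.44 (camera adjusted p = 3.0e-18, and adjusted p = 0.00026 with an estimated correlation). Tight junction genes had 2 increases, and 5 adjusted over the list alone (adjusted p = 0.0026 with an estimated correlation). Cholesterol synthesis genes had 0 changes by limma over all genes and 7 increases adjusted over the list alone, with a median of 0.26 (camera adjusted p = 5.2e-12, and adjusted p = 0.0012 with an estimated correlation). The 15 mesenchymal genes had a median of -0.21 (camera adjusted p = 0.0025, and adjusted p = 0.059 with an estimated correlation). The total of 37 genes was 24 and 22 without the ethanol libraries of replicates 1 and 2 and 22 without the tamoxifen library of replicate 3. It was 242 with array weights, 174 with the libraries of the contrast alone, 66 without the libraries that stood apart and 21 with voom weights.

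The response itself differed between 16 h and 8 h in Kmt2c-KO cells for 8 genes. Aldh3b2 (-1.94 ± 0.28; limma adjusted p = 2.0e-03), Pmp22 (-1.71), Endod1 (-1.44) and Rhox6 (-1.32) responded less at 16 h. The size for Aldh3b2 depends on the pseudocount, because it was listed at 0 in the ethanol libraries at 8 h. Apela (0.82 ± 0.15) and Lefty2 (0.81 ± 0.15), whose RNA fell at 8 h, had a smaller fall at 16 h. Il17re (-1.60 ± 0.30) and Klhl13 (-0.90 ± 0.16) were added outside the naming rule after their values were seen. The count was 3, 4, 5, 3 and 4 without the 8 h ethanol libraries of replicates 1 and 3 and the 8 h tamoxifen libraries of replicates 1, 2 and 3. It was 1, 5, 3, 5, 3 and 2 without the 16 h ethanol libraries and the 16 h tamoxifen libraries of replicates 1 to 3, in that order. It was 89 with array weights, 36 without the libraries that stood apart, 28 with a pseudocount of 5 and 26 with the contrast's libraries alone, and the split of 2 above and 6 below 0 became 4 and 6 with median-of-ratios scaling.

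Tamoxifen in GRHL2-ERT double-KO cells, which asks what nuclear GRHL2 changes without KMT2D, raised 8 genes and lowered 4 at 8 h. Tmem54 rose from 0.355 ± 0.373 to 3.65 ± 0.916 CPM (1.80 ± 0.25; limma adjusted p = 4.1e-04). Epcam, an epithelial adhesion gene (chromosome 17, 87635979 to 87651129), rose from 18.4 ± 1.75 to 45.9 ± 8.75 CPM (1.26 ± 0.15; adjusted p = 3.1e-05). Cldn4 (chromosome 5, 134945119 to 134946934) rose from 68.4 ± 7.74 to 132 ± 27.0 CPM (0.92 ± 0.13; adjusted p = 7.4e-04). Anxa9 (1.44), Ppl (1.32), Wfdc2 (0.85), Arap2 (0.77) and Fabp3 (0.50) also rose. The neural adhesion gene Ncam1 (-0.74 ± 0.12), Lefty2 (-0.65 ± 0.11), Ccnd3 (-0.62 ± 0.12) and Gm13889 (-1.20 ± 0.24; outside the naming rule, chosen after its value was seen) fell. In Kmt2c-KO cells at 8 h, 6 of the 8 increases and all 4 decreases were called as well, where independence gives 0.233 and 0.0815. Of 40 GRHL2 targets 3 rose (Cldn4, Epcam and Ppl) and 9 adjusted over the list alone, with a median of 0.16 (camera adjusted p = 7.5e-06, and adjusted p = 0.087 with an estimated correlation). Mesenchymal genes had 0 changes by limma over all genes and 8 of 15 below 0 adjusted over the list alone, with a median of -0.48 (camera adjusted p = 0.0024, and adjusted p = 0.11 with an estimated correlation). The count of 12 was 4 and 54 without the ethanol libraries of replicates 2 and 3, and 106 and 3146 without the tamoxifen libraries of replicates 1 and 3. It was 0 with limma on the libraries of the contrast alone, 1 with array weights and 36 with a pseudocount of 5, against 2520 genes at an unadjusted p under 0.05. With median-of-ratios scaling 11 genes rose and 2 fell. Data simulated with each group's own spread gave 67.7% false calls for this contrast, or 405 per run beside 200 changed genes. That simulation drew noise for each gene alone and called many more genes than 12, so its share need not hold for the 12. The tamoxifen library of replicate 2 had the lowest depth, the lowest mean correlation within its group (0.938) and 7.37% of its reads from Rn45s.

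At 16 h in double-KO cells 4 genes rose and 1 fell. Tmem54 rose from 0.480 ± 0.286 to 5.23 ± 0.510 CPM (2.09 ± 0.25; limma adjusted p = 4.3e-05). Epcam rose from 14.6 ± 1.85 to 32.0 ± 4.87 CPM (1.08 ± 0.15; adjusted p = 3.0e-04), Cldn4 by 0.89 ± 0.13 (adjusted p = 1.3e-03) and Arap2 by 0.67 ± 0.12 (adjusted p = 2.1e-02). Spats2l fell by 0.94 ± 0.18 (adjusted p = 4.9e-02). These 4 increases were also called at 8 h, where independence gives 0.00258. The GRHL2 targets had 2 increases, and 3 adjusted over the list alone, with a median of 0.21 (camera adjusted p = 1.5e-08, and adjusted p = 0.011 with an estimated correlation). Cholesterol synthesis genes had 0 changes by limma over all genes and 7 increases adjusted over the list alone, with a median of 0.29 (camera adjusted p = 4.5e-12, and adjusted p = 0.002 with an estimated correlation). Mesenchymal genes had 0 changes over all genes and 3 decreases adjusted over the list alone, with a median of -0.19 (camera adjusted p = 0.00045, and adjusted p = 0.031 with an estimated correlation). At an unadjusted p under 0.05 there were 519 genes. The count of 5 was 3 without any 1 of the ethanol libraries of replicates 1, 2 and 3, and 8 and 3 without the tamoxifen libraries of replicates 1 and 2. It was 206 with array weights, 11 without the libraries that stood apart and 9 with a pseudocount of 5, and with median-of-ratios scaling 3 rose and 0 fell. The response differed between 16 h and 8 h for 0 genes by limma in double-KO cells, with 714 at an unadjusted p under 0.05.

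The question of whether loss of KMT2D changes the response to GRHL2 was addressed by the difference between the lines' tamoxifen responses. At 8 h the increase was smaller in double-KO than in Kmt2c-KO cells for Wnt7b (difference of log2 fold changes -2.71 ± 0.33; limma adjusted p = 5.2e-05) and Acsl5 (-2.32 ± 0.30; adjusted p = 8.3e-05). The response was also smaller for Cgn (-2.74 ± 0.50), Bnipl (-2.44 ± 0.39) and Aldh3b2 (-3.04 ± 0.28), whose size depends on the pseudocount because its ethanol libraries were listed at 0. The difference for Cgn was larger than its rise in Kmt2c-KO cells, so Cgn did not rise in double-KO cells. In double-KO cells with tamoxifen at 8 h, Wnt7b reached 1.54 ± 0.525 CPM and Acsl5 6.85 ± 0.371 CPM, against 20.8 ± 3.52 and 24.7 ± 1.06 CPM in Kmt2c-KO cells. Epcam (0.49 ± 0.21; adjusted p = 0.15) did not pass the test of a difference. Utf1 (1.33 ± 0.18), Tcl1 (1.05) and Sox2 (0.70 ± 0.14), which fell in Kmt2c-KO cells, had a response that was less negative in double-KO cells, where Tcl1 already stood at 1.37 ± 0.621 CPM in ethanol. Of 40 GRHL2 targets 4 had a smaller response, among them Cgn, Cldn6 and Mal2, and 6 adjusted over the list alone, with a median of -0.49 (camera adjusted p = 0.013, and adjusted p = 0.50 with an estimated correlation).

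Over all genes 177 responses differed between the lines at 8 h, 65 above and 112 below 0. The largest differences above 0 were those of Etnk2 (1.81 ± 0.46), Platr26 (1.78 ± 0.32), Chst15 (1.73 ± 0.42) and Sgk2 (1.55 ± 0.33). With median-of-ratios scaling, which shifted all genes by 0.10, 102 lay above and 118 below. The total was 63 and 609 without the Kmt2c-KO ethanol libraries of replicates 1 and 2, and 72 and 59 without the Kmt2c-KO tamoxifen libraries of replicates 1 and 2. It was 60, 71 and 747 without the double-KO ethanol libraries and 458, 100 and 3090 without the double-KO tamoxifen libraries of replicates 1 to 3, in that order. It was 9 with array weights, 5 with the libraries of the contrast alone, 17 with Rn45s as a covariate and 294 with a pseudocount of 5. Simulated data with each group's own spread, and noise drawn for each gene alone, gave 37.5% false calls for this contrast. That share need not hold for the 177. At 16 h 0 genes differed by limma and 315 had an unadjusted p under 0.05, in a test that recovered 54.8% of simulated differences of log2 1 with a spread pooled over groups. With array weights 18 differed, and 1 differed without the Kmt2c-KO ethanol library or without the double-KO tamoxifen library of replicate 3.

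Induced genes as a set responded less in double-KO cells at both times. The 37 genes chosen at 8 h, among them Esrp1 and Wnt7b, had a median tamoxifen response at 16 h of 0.94 in Kmt2c-KO and 0.57 in double-KO cells. Their median difference was -0.52 ± 0.52 (SD over 37 genes) and 30 of 37 were smaller in double-KO cells (limma fry adjusted p = 3.2e-06 over the 3 sets, and camera adjusted p = 6.6e-07 with an estimated correlation). Epcam, also in this set, went the other way, with responses of 0.43 in Kmt2c-KO and 1.08 in double-KO cells. The median difference at 16 h was -0.19 with a pseudocount of 5, -0.91 with one of 0.1, -0.87 with the deposited log2 values, -1.0 with voom weights, -0.84 over 12 genes chosen at the same time point and -0.22 over 172 genes with an average of at least 0.5. The 12 genes chosen at 16 h had a median response at 8 h of 2.34 in Kmt2c-KO and 0.59 in double-KO cells. Their median difference was -1.67 ± 0.74 (SD over 12 genes) and 12 of 12 were smaller (fry adjusted p = 1.6e-12, and camera adjusted p = 6.6e-07 with an estimated correlation). The median difference at 8 h was -1.07 over 37 genes chosen at the same time point and -0.82 over 54 genes with an average of at least 0.5. With genes listed at 0 in a group, Aldh3b2 in the first set and Lypd2 in the other, at their bound, the medians were -0.52 and -1.69. The slopes of double-KO on Kmt2c-KO responses were 0.50 at 16 h and 0.27 at 8 h. The 81 genes repressed on average at 8 h had medians at 16 h of -0.32 in Kmt2c-KO and -0.16 in double-KO cells, a median difference of 0.07 ± 0.32 (SD over 81 genes; fry adjusted p = 0.13). Their slope was 0.63, and 28 of 81 were more negative in double-KO cells. The unadjusted camera p was 0.043 at the preset correlation and 0.14 with an estimated correlation. The median difference was -0.27 over 7 genes chosen at the same time point (unadjusted fry p = 0.015, and unadjusted camera p = 0.0040 with an estimated correlation). Each genotype was 1 line and Grhl2 tags were higher in the Kmt2c-KO line, as given above for each group.

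**Figure D2:**
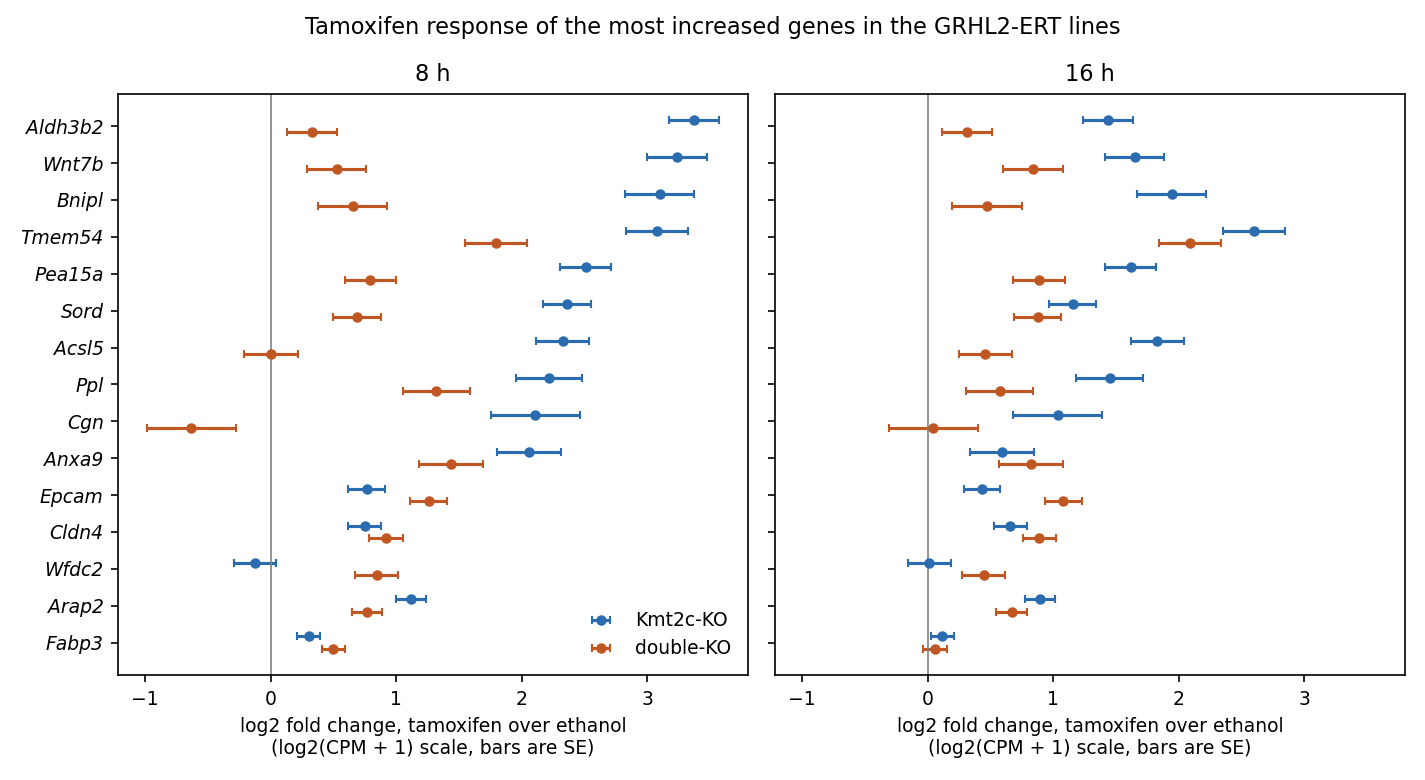
Log2 fold change with tamoxifen ± SE for 15 named genes at 8 h and at 16 h, in GRHL2-ERT Kmt2c-KO cells (blue) and double-KO cells (orange), 3 libraries per group. At 8 h Wnt7b reached 3.24 in Kmt2c-KO cells, while Tmem54 rose in both lines, by 3.08 and 1.80.

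**Figure D3:**
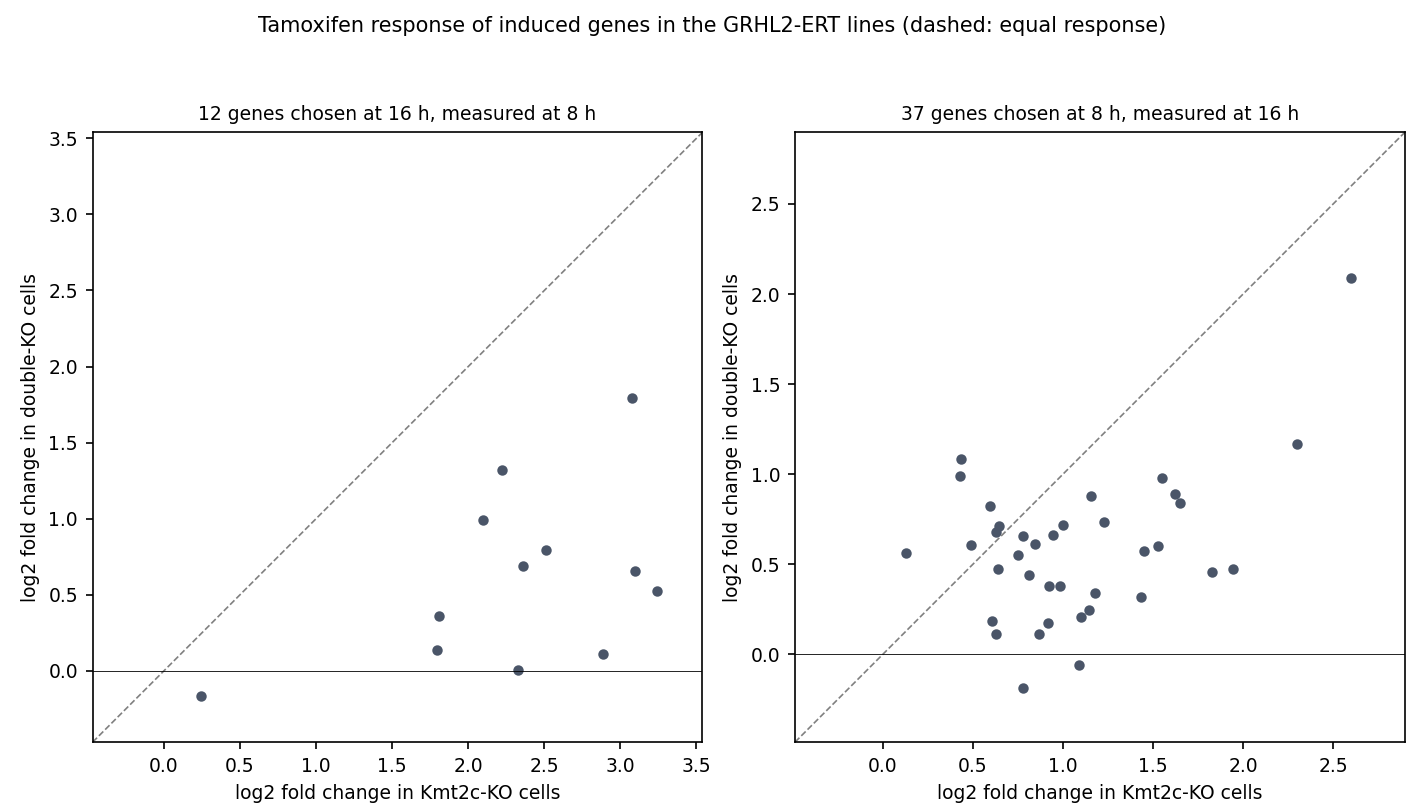
Log2 fold change with tamoxifen in double-KO cells against Kmt2c-KO cells, with each point 1 induced gene and the dashed line equal responses; 12 genes chosen at 16 h are shown at 8 h and 37 chosen at 8 h are shown at 16 h. Points lie below the line for 12 of 12 genes at 8 h and 30 of 37 at 16 h.

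Tamoxifen-treated Kmt2c-KO cells with and without GRHL2-ERT were compared to ask what depends on the transgene. They were different lines, so effects of line and transgene cannot be told apart. At 8 h Grhl2 (5.57 ± 0.25), Esr1 (3.62 ± 0.47), Bnipl (3.45) and Aldh3b2 (3.38) were higher with GRHL2-ERT, and Aldh3b2 was listed at 0 in all 3 libraries without it. Trh (-2.02), N-cadherin, Cdh2 (-1.62), Pnp2 (-1.48) and Etv1 (-1.47) were lower. Of 40 GRHL2 targets 19 were higher, 27 higher and 1 lower adjusted over the list alone, with a median of 0.83 (camera adjusted p = 8.2e-27, and adjusted p = 1.8e-05 with an estimated correlation). Of 9 keratin genes 4 were higher (Krt7, Krt8, Krt18 and Krt19), and 5 higher and 1 lower adjusted over the list alone (adjusted p = 0.015 with an estimated correlation). In all 332 genes were higher and 173 lower. Among the 362 genes raised by tamoxifen at 8 h, 203 were also higher here, where independence gives 9.68, and 100 of the 253 that fell were lower, where it gives 3.53. Part of this excess may come from the tamoxifen libraries that both contrasts share, and the expected values leave these out. Simulated unchanged groups with the same sharing had 0 shared calls, which the lack of changes fixes. With a spread pooled over all 10 groups, they had a covariance of log2 fold changes over all genes of 0.0303, against 0.0890 measured. The total of 505 was 333 without the library of replicate 1 without GRHL2-ERT, 295 and 336 without the GRHL2-ERT libraries of replicates 2 and 3, 1254 with array weights, 1044 with the libraries of the contrast alone and 895 without the libraries that stood apart.

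At 16 h Grhl2 (4.83), Esr1 (3.02) and Tmem54 (2.26) were higher with GRHL2-ERT, among 80 higher and 41 lower genes. The largest decreases were the Y-linked Eif2s3y (-1.59), Zscan4c (-1.52 ± 0.22), Actn3 (-1.50) and Zscan4a (-1.35). Eif2s3y had 4.44 ± 0.815 CPM without GRHL2-ERT at 16 h, and with it 0.849 ± 0.527 CPM in tamoxifen and 0.467 ± 0.134 CPM in ethanol. Zscan4c and Eif2s3y were also lower in ethanol-treated GRHL2-ERT cells against the same tamoxifen-treated cells, as given below. The decreases of these genes thus did not need tamoxifen in the GRHL2-ERT line. An effect of tamoxifen in the cells without GRHL2-ERT is not excluded, because those had tamoxifen in both comparisons. Of 6 measured genes of the 2-cell-like state 3 were lower (Tcstv1, Zscan4a and Zscan4c), and 4 adjusted over the list alone, with a median of -1.05 (camera adjusted p = 3.3e-08, and adjusted p = 0.00013 with an estimated correlation). Zscan4 genes are near-identical copies, so tags of single members are uncertain. Of 40 GRHL2 targets 5 were higher and 8 adjusted over the list alone (adjusted p = 0.0074 with an estimated correlation). Among the 36 genes raised by tamoxifen at 16 h, 28 were higher, where independence gives 0.232, and part of this excess may come from the shared tamoxifen libraries. The covariance of log2 fold changes over all genes was 0.0334, against 0.0307 in simulated unchanged groups with the same sharing, which had 0 shared calls because nothing changed in them. The simulation used a spread pooled over all 10 groups. The shared tamoxifen libraries had mean correlations within their group of 0.991, against 0.938 for the lowest library. The simulated covariance may thus be too high for them and does not show how much came from sharing. The total of 121 was 70, 68 and 75 without each library lacking GRHL2-ERT and 78, 65 and 61 without each GRHL2-ERT library, in order of replicate. It was 625 with array weights, 259 with the contrast's libraries alone and 76 with voom weights.

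Ethanol-treated GRHL2-ERT cells were compared with tamoxifen-treated cells without GRHL2-ERT, a comparison in which drug, transgene and line all differ. At 8 h 10 genes were higher, among them Grhl2 (5.62), Esr1 (2.71), the imprinted RNA Meg3 (1.52 ± 0.15) and Pxylp1 (1.35), and 3 were lower, Serpina3m (-1.76), Eif2s3y (-1.36) and Ddx3y (-1.22 ± 0.13). At 16 h 9 were higher, among them Grhl2 (4.83), Esr1 (2.95), H2-Eb1 (0.98) and Meg3 (0.77), and 12 were lower, among them Plac9a (-2.50), Eif2s3y (-1.88), Zscan4c (-1.40) and Ddx3y (-1.30). Of 6 genes of the 2-cell-like state 1 was lower at 16 h and 5 adjusted over the list alone, with a median of -0.87 (adjusted p = 7.0e-05 with an estimated correlation). With median-of-ratios scaling 10 were higher and 6 lower at 8 h, and 3 higher and 17 lower at 16 h.

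The count of 13 for these controls at 8 h was 5, 6 and 6 without each library lacking GRHL2-ERT and 6 without the GRHL2-ERT library of replicate 1 or of replicate 3. It was 38 with array weights, 106 without the libraries that stood apart and 6 with Rn45s as a covariate. The count of 21 at 16 h was 12, 13 and 11 without each library lacking GRHL2-ERT and 7, 6 and 11 without each GRHL2-ERT library, in order of replicate. It was 274 with array weights, 128 with the contrast's libraries alone, 39 with Rn45s as a covariate and 33 with a pseudocount of 5.

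Double-KO and Kmt2c-KO cells with GRHL2-ERT in ethanol, compared to ask how the lines differ before GRHL2 acts, differed in about the same number of genes at each time, 6136 at 8 h and 6203 at 16 h. At 8 h the neural transcription factor gene Sox1 had 0.803 ± 0.438 CPM in Kmt2c-KO and 60.1 ± 8.52 CPM in double-KO cells (log2 fold change 5.11 ± 0.20; limma adjusted p = 9.1e-18). Dppa3, a gene of naive and germline cells, had 58.7 ± 7.56 and 1.23 ± 0.976 CPM (-4.82 ± 0.23; adjusted p = 4.7e-16), and the Nodal antagonist gene Lefty1 was lower (-4.08). The X-linked Xlr3a (6.08 ± 0.19), Xlr3b (5.76), Xlr4b (5.37) and Xlr4a (5.16), near-identical copies whose single values are uncertain, were higher, as were Pnma5 (4.92), Emp1 (4.67) and the Y-linked Eif2s3y (5.23 ± 0.28). Lower genes were Pla2g1b (-5.90 ± 0.19), Ephx2 (-4.64), Mcf2 (-4.22), Pla1a (-4.19), Srrm4os (-3.93) and Slc28a1 (-3.92). At 16 h smooth muscle actin, Acta2, had 0.947 ± 0.115 and 151 ± 11 CPM (6.28 ± 0.25; adjusted p = 2.0e-17), and the imprinted Peg10 had 16.3 ± 2.53 and 557 ± 41.4 CPM (5.02 ± 0.16; adjusted p = 1.5e-19). Igfbp5 (4.80), Xlr3a (5.46) and Eif2s3y (5.44) were also higher at 16 h, and Pla1a (-5.02), Mcf2 (-4.89), Pla2g1b (-4.81), Myo1f (-4.56) and Gpa33 (-4.26) were lower.

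In double-KO cells 4664 genes were higher and 1472 lower at 8 h, and 4967 and 1236 at 16 h. The median of all genes lay at 0.31 and 0.35, so changes are best read relative to it. With median-of-ratios scaling, which shifted values by -0.29 and -0.34, 2592 were higher and 2644 lower at 8 h, and 2576 and 2574 at 16 h. Of the higher genes 3435 were shared by both times, where independence gives 1866, and of the lower genes 834, where it gives 147. With a log2 fold change of at least 1 the totals were 2237 and 2272. Relative to the median shift, that is with scaling, 11 of 15 mesenchymal genes were higher and 2 lower at each time, against 12 and 2 at 8 h and 13 and 1 at 16 h as deposited, with the same counts as deposited adjusted over the list alone. That list included Zeb1 (0.89 ± 0.17 at 8 h), Vim (1.43 ± 0.17) and Cdh2 (2.60 ± 0.24), and had an adjusted p = 0.13 and 0.16 with an estimated correlation. With scaling, 14 of 20 p53 targets were higher and 3 lower at 8 h, and 12 and 3 at 16 h, against 15 and 3 as deposited and adjusted over the list alone (adjusted p = 0.13 and 0.12 with an estimated correlation). They included Cdkn1a, the cell cycle inhibitor gene (1.35 ± 0.11 at 8 h, 2.10 ± 0.11 at 16 h). With scaling, 10 of 22 naive pluripotency genes were lower and 5 higher at 8 h, and 12 and 2 at 16 h, against 9 and 6, and 11 and 5, as deposited. Adjusted over the list alone 10 and 12 were lower (adjusted p = 0.13 and 0.12 with an estimated correlation). Klf4 was higher at both times (1.28 ± 0.13 and 1.07 ± 0.13) and Tcl1 lower (-3.05 ± 0.18 and -3.49 ± 0.18). GRHL2 targets had 7 higher and 13 lower at 8 h as deposited and adjusted over the list alone (adjusted p = 0.13 with an estimated correlation), and 13 higher and 4 lower at 16 h (adjusted p = 0.97 with an estimated correlation). Their median at 16 h was 0.18 as deposited and -0.01 with scaling.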

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

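The split scheme for the differences of responses and the 3 tests of the smaller response in double-KO cells were chosen only after the results were seen; the splits of single contrasts and the test of each difference by limma were fixed earlier.

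The tamoxifen response differed between the lines at 8 h by limma's test of the difference for 177 genes and between the times in Kmt2c-KO cells for 8 genes. Larger or less negative responses in double-KO cells were those of Etnk2 (1.81), Platr26 (1.78), Chst15 (1.73), Sgk2 (1.55), Rap1gap (1.52) and Axl (1.48), as differences of log2 fold changes. Smaller responses were those of Aldh3b2 (-3.04), Cgn (-2.74), Wnt7b (-2.71), Bag2 (-2.53), Bnipl (-2.44), Acsl5 (-2.32), Plac8 (-2.25), Msrb3 (-2.04) and H2-D1 (-1.99). Between 16 h and 8 h in Kmt2c-KO cells, Apela (0.82) and Lefty2 (0.81) differed upward, and Aldh3b2 (-1.94), Pmp22 (-1.71), Endod1 (-1.44) and Rhox6 (-1.32) downward.

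Some lists differed between lines or times by camera at the preset correlation. At 8 h the median difference between lines was -0.40 for cholesterol synthesis genes and -0.49 for GRHL2 targets, and both calls were lost with an estimated correlation (adjusted p = 0.50). At 16 h it was -0.16 for estrogen receptor targets, a call that held (adjusted p = 0.037 with an estimated correlation). Between 16 h and 8 h in Kmt2c-KO cells, medians were -0.39 for desmosome genes, 0.18 for formative genes, -0.45 for GRHL2 targets, 0.17 for mesoderm genes, 0.20 for naive pluripotency genes and -0.44 for trophoblast genes. The formative call was lost (adjusted p = 0.095 with an estimated correlation), as were the others (adjusted p = 0.080 with an estimated correlation). In double-KO cells, cholesterol synthesis genes (0.29) and genes of the COMPASS complexes (0.34) differed between times, both lost with an estimated correlation (adjusted p = 0.32 and 0.61).

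Induced genes rose less in double-KO cells, with a median difference of -0.52 at 16 h and -1.67 at 8 h. A poor library does not account for it, since the difference at 8 h was -1.70 without the double-KO tamoxifen library of replicate 2. For a compressed log scale, the difference at 16 h was -0.91 with a pseudocount of 0.1 and -0.19 with one of 5, which compresses more. The medians of both lines moved too, to 1.61 in Kmt2c-KO and 0.90 in double-KO cells with 0.1, and to 0.44 and 0.27 with 5. The size of the difference thus cannot decide on compression, though the double-KO median was the smaller one with each pseudocount. A lower level of GRHL2-ERT in double-KO cells may contribute and stays open. Grhl2 tags with tamoxifen were 1.35 times higher in Kmt2c-KO cells at 16 h and 2.17 times higher at 8 h. The responses also lay farther apart at 8 h, with a median difference of -1.69 at 8 h and -0.84 at 16 h over the 10 genes chosen at both times. The ratio at 8 h was held down by the double-KO tamoxifen library of replicate 2, with 125 CPM of Grhl2 against 58.6 and 51.2 CPM in replicates 1 and 3. Esr1 tags with tamoxifen were 6.77 times higher in Kmt2c-KO cells at 8 h and 2.00 times higher at 16 h, and replicate 2 had 1.02 CPM of Esr1 at 8 h. In ethanol at 8 h Esr1 had 31.2 ± 18.7 CPM in Kmt2c-KO and 13.9 ± 4.22 CPM in double-KO cells. In Kmt2c-KO cells with tamoxifen, Grhl2 had 170 CPM at 8 h and 77.5 CPM at 16 h, while Esr1 had 53.6 and 61.2 CPM. Tags of these genes thus did not move together, and the level of GRHL2-ERT itself is uncertain. Loss of KMT2D stays open as well and was not tested, because each genotype was 1 line. A model with several clones per genotype at matched GRHL2 levels could part these.

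Exchanging the line labels within each treatment, after centring each line, tested the differences between lines over 100 splits, the real one included. For the medians over induced genes 1 split, the real one, was as far from 0 at 8 h (real -1.67, highest other 1.31) and at 16 h (real -0.52, highest other 0.41). This does not exclude chance, because the scheme was chosen after another had been seen and treats libraries of both lines as exchangeable. The double-KO tamoxifen libraries at 8 h had mean correlations within their group of 0.938 to 0.965, against 0.987 to 0.989 in Kmt2c-KO cells. For the 177 genes at 8 h 8 splits gave as many (highest other 3294), so chance could not be excluded, and splits with many more genes than the real one point to a structure among the 8 h libraries. For the repressed genes 13 splits were as far from 0 (real 0.07, highest other -0.094), so chance could not be excluded. The 0 genes at 16 h by limma (315 at an unadjusted p under 0.05) were matched by all 100 splits (highest other 1), which a count of 0 fixes. Exchanging time labels gave 1 split, the real one, with as many as 8 genes in Kmt2c-KO cells (highest other 1). That scheme too was chosen after another had been seen, so it does not exclude chance. For the 0 genes in double-KO cells (714 at an unadjusted p under 0.05) all 100 splits gave as many (highest other 2310).

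A first scheme exchanged the drug labels within each line or time, and was replaced after its result was seen because it turns the drug effect itself into a difference between lines. Under that scheme chance was not excluded for any of these results. Of 100 splits, 13 gave at least 177 genes (highest other 3437), 12 a median as far as -1.67 at 8 h (2.77), 38 one as far as -0.52 at 16 h (1.19) and 70 one as far as 0.07 for repressed genes (-0.42). The 8 genes between times in Kmt2c-KO cells were matched by 12 splits (192), and both counts of 0 by all 100 (13 between lines at 16 h, and 2016 between times in double-KO cells).

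The 10 splits of 3 libraries against 3 are too few for a share under 0.05. For tamoxifen in Kmt2c-KO cells the real split gave 615 genes at 8 h and 37 at 16 h, and the highest other gave 0 at each time; 1 of 10 splits, the real one, gave as many. In double-KO cells 12 genes at 8 h were matched by 2 of 10 splits, and the other split, which parts ethanol replicates 1 and 2 with tamoxifen replicate 3 from the rest, gave 3288 and points to a structure among these libraries. At 16 h the 5 genes had 0 as the highest other. Between lines in ethanol the real splits gave 6136 and 6203 genes and the highest others 9 and 0. The comparisons with cells without GRHL2-ERT gave 505, 121, 13 and 21 genes, each with 0 as the highest other.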

How the results depend on the processing

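Alternatives added after the data were seen were median-of-ratios scaling (fixed earlier for the medians over induced and repressed genes), the deposited log2 values, voom weights, array weights, Rn45s as a covariate and the fit without 3 libraries that stood apart. No filter, and a replicate block over all libraries, left every count within 1.5 times its value. Choosing induced genes at an average of at least 0.5 gave medians of -0.22 at 16 h and -0.82 at 8 h, with the same direction and call. For all values below the cause was not tested, except where fewer genes or libraries enter by construction. Counts of genes are named here as K (tamoxifen in Kmt2c-KO), D (tamoxifen in double-KO), L (difference between lines), T (difference between times in Kmt2c-KO), G (lines in ethanol), W (tamoxifen with and without GRHL2-ERT) and C (ethanol with against tamoxifen without GRHL2-ERT), followed by the time in hours. Replicate numbers did not pair libraries, since 12 correlations of paired residuals ran from -0.58 to 0.13, 1 passed 0.1 and 2 were best with their own number. With a replicate block within line and time, K 8 h was 293, K 16 h 17, D 8 h 3, D 16 h 1 and L 8 h 12. With array weights, K 8 h was 1116, K 16 h 242, D 8 h 1, D 16 h 206, L 8 h 9, L 16 h 18, T 89, W 8 h 1254, W 16 h 625, C 8 h 38 and C 16 h 274. Without the libraries that stood apart, K 8 h was 1380, K 16 h 66, D 16 h 11, T 36, W 8 h 895 and C 8 h 106. Among these contrasts only D 16 h held any of those libraries, and for the others only the shared spread changed. With a log2 fold change of at least 1, K 8 h was 204, K 16 h 24, D 8 h 5, D 16 h 2, G 8 h 2237, G 16 h 2272, T 5, W 8 h 206, W 16 h 49 and C 16 h 12. With the libraries of the contrast alone, K 16 h was 174, D 8 h 0 by limma, L 8 h 5, T 26, W 8 h 1044, W 16 h 259 and C 16 h 128. With a pseudocount of 5, D 8 h was 36, D 16 h 9, L 8 h 294, T 28 and C 16 h 33. With Rn45s as a covariate, L 8 h was 17, T 14, C 8 h 6 and C 16 h 39. With voom weights, K 16 h was 21, T 4 and W 16 h 76. With a pseudocount of 0.1 or the deposited log2 values, T was 5, and with median-of-ratios scaling D 16 h was 3.

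The median difference over repressed genes passed its test with median-of-ratios scaling (0.061), Rn45s as a covariate (0.12) and without the libraries that stood apart (0.079) by fry, with an unadjusted camera p = 0.0088, 0.13 and 0.16 with an estimated correlation. It reversed over 7 genes chosen at the same time point (-0.27), with an unadjusted fry p = 0.015 and camera p = 0.0040 with an estimated correlation. Leaving out 1 library gave 320 to 604 for K 8 h, 22 to 27 for K 16 h, 4 to 3146 for D 8 h, 3 to 8 for D 16 h, 59 to 3090 for L 8 h and 0 to 1 for L 16 h. It gave 4999 to 5956 for G 8 h, 5336 to 5466 for G 16 h, 1 to 6 for T, 0 for the times in double-KO cells by limma (714 at an unadjusted p under 0.05 over all libraries), 295 to 351 for W 8 h, 61 to 78 for W 16 h, 5 to 10 for C 8 h and 6 to 13 for C 16 h. Medians ran from -0.61 to -0.45 for induced genes at 16 h, -1.74 to -1.56 at 8 h and 0.03 to 0.12 for repressed genes. Among these, leaving out double-KO tamoxifen replicate 3 at 8 h gave the 3146 for D and 3090 for L, and leaving out Kmt2c-KO tamoxifen replicate 2 at 8 h the 320 for K, 59 for L and 295 for W at 8 h, while other libraries lay behind the other limits. With 2 libraries left in a group the spread came from all groups. Depth limits genes near the floor of 3 reads, 0.136 to 0.339 CPM.

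Of 380 results for 199 named genes 0 reversed, which was likely from the start because only called genes were kept and the same libraries were refitted. Those no longer past the threshold numbered 106 with the fold threshold, 46 with the contrast's libraries alone, 39 with Rn45s, 36 with array weights, 33 with voom weights, 28 with a pseudocount of 0.1, 23 with the deposited values, 18 with scaling, 16 without the libraries that stood apart, 6 with the replicate block and 5 with a pseudocount of 5. They also numbered 56 of 109 with a replicate block within line and time and 348 of 2496 over the fits that left out 1 library. Of 70 list calls 39 were lost with an estimated correlation, 14 with fry, 7 without the libraries that stood apart and 1 with the replicate block. Count models were not run as the main test because the values are log2. The count model on recovered reads that was fixed as an added alternative was not run either. An average log2 fold change of at least 2 left too few genes to test.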

Other observations

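The tests of the cholesterol genes and that of regions of chromosome 8 were chosen only after the results were seen, while the other tests of the chromosomes were written before their results.

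Genes of other lineages were also called between double-KO and Kmt2c-KO cells in ethanol, counted here with median-of-ratios scaling because all genes were shifted. None of these lists passed with an estimated correlation, so the counts mark no lineage as a set. Of all 12414 genes 2592 were higher and 2644 lower at 8 h with scaling, and 2576 and 2574 at 16 h. Of 12 neuroectoderm genes 6 were higher and 0 lower at 8 h, and 6 and 1 at 16 h, with Sox1 highest in fold (5.11 and 3.86). As deposited and adjusted over the list alone 8 were higher at each time (adjusted p = 0.17 and 0.24 with an estimated correlation). Of 8 fibroblast genes 2 were higher at 8 h and 6 at 16 h and 0 were lower, with Acta2 (3.63 and 6.28), Col1a1 (0.70 and 1.06) and Col1a2 (1.28 and 1.57) among the higher ones as deposited, while Thy1 did not differ past the threshold (-0.07 and -0.01). As deposited and adjusted over the list alone 6 and 7 were higher (adjusted p = 0.20 and 0.12 with an estimated correlation). Of 17 trophoblast genes 7 were higher and 3 lower at 8 h, and 10 and 2 at 16 h, with Krt8, Krt18, Gata2 and Peg10 among the higher ones at 16 h (adjusted p = 0.60 and 0.16 with an estimated correlation). Of 20 genes of COMPASS complexes and enhancer co-activators 4 were higher and 7 lower at 8 h, and 5 and 4 at 16 h (adjusted p = 0.93 and 0.76 with an estimated correlation).

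Y-linked genes were measured at different levels in the lines. Ddx3y had 47.4 ± 2.79 CPM (SD, n = 3) in Kmt2c-KO cells without GRHL2-ERT at 8 h, 19.8 ± 1.35 CPM in the GRHL2-ERT Kmt2c-KO line in ethanol and 115 ± 8.24 CPM in the double-KO line. Eif2s3y had 2.08 ± 0.859, 0.181 ± 0.161 and 43.4 ± 7.29 CPM in the same groups. Zscan4c, a gene of the 2-cell-like state with near-identical copies, had 0.677 ± 0.251 CPM at 8 h and 17.6 ± 1.62 CPM at 16 h in cells without GRHL2-ERT.

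Median differences between double-KO and Kmt2c-KO cells in ethanol varied by chromosome over 11511 genes on 19 autosomes. Chromosome 17 lay at -0.39 at 8 h and -0.35 at 16 h, chromosome 14 at -0.28 and -0.35, and chromosome 8 at 0.31 and 0.22, with the median of all genes taken out. GC content and gene length were argued against, since the range of the medians at 16 h was 0.57 after regression on them and on level, against 0.19 as the highest of 1000 shuffles. Medians of the genes nearer the start and nearer the end of each autosome went together at 8 h by Pearson's r. They did not pass by Spearman's rho once adjusted, as given below. A cause in a few regions is thus not decided over the autosomes as a set. Chromosomes 9 (-0.34 and -0.27) and 12 (-0.24 and -0.23) were low in both parts at 8 h, while chromosomes 6 (0.25 and -0.012) and 16 (0.17 and -0.13) differed between parts. Chromosome 17 lay at -0.45 and -0.32 in these parts and chromosome 14 at -0.29 and -0.26, while chromosome 8 lay at 0.60 and -0.0057 (0.38 and 0.04 at 16 h), so that its shift came from 1 part and a regional cause stays open there. Both parts had the same sign on 12 of 19 autosomes at 8 h and 13 of 19 at 16 h. Pearson's r at 8 h was 0.67 (permutation p = 0.00218, adjusted p = 0.00327 over 3 contrasts, and r = 0.72 without the 2 farthest chromosomes), while Spearman's rho was 0.46 (permutation p = 0.0466, adjusted p = 0.0789). Different chromosome copies in the lines may contribute and stay open, as does loss of KMT2D, which was not tested, with r = 0.73 at 16 h (permutation p = 0.00065, adjusted p = 0.00195, and r = 0.52 without the 2 farthest) and rho = 0.46 (permutation p = 0.0526, adjusted p = 0.0789). Ethanol-treated GRHL2-ERT cells against tamoxifen-treated cells without it, both Kmt2c-KO, at 16 h had r = -0.07 (permutation p = 0.71, adjusted p = 0.71). Their range of medians was smaller, at 0.16 and 0.13 after regression, but also passed the highest of the shuffles (0.08 and 0.07). Chromosome 3 lay highest, at 0.13, with -0.0021 in the genes nearer the start and 0.26 in those nearer the end. Double-KO against Kmt2c-KO cells in ethanol at 16 h had 0.12 and -0.20 in these parts of chromosome 3, and the cause was not tested. At 8 h the comparison with cells without GRHL2-ERT passed before regression (0.105, highest shuffle 0.0887) and not after it (0.0774, 0.0880). Tamoxifen in Kmt2c-KO cells at 8 h, within 1 line, did so too (0.107, 0.0995, and after regression 0.0959, 0.103). A range just past the shuffles, like these at 8 h, thus does not by itself mark a difference between lines.

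Cholesterol synthesis genes were higher with tamoxifen at 16 h in both lines, with medians of 0.26 and 0.29. Above 0 lay 22 of 26 members (84.6%) in double-KO cells and 23 of 26 in Kmt2c-KO cells. A few genes cannot carry a median, so this count describes the list and could hardly have failed as a test. An effect of tamoxifen that needs no GRHL2-ERT may contribute and could not be parted from one that does, since tamoxifen-treated cells with GRHL2-ERT lay at a median of 0.12 above those without it (adjusted p = 0.20 with an estimated correlation), and ethanol-treated GRHL2-ERT cells at -0.14. Ethanol-treated cells without GRHL2-ERT were not analysed here. At 8 h 25 of 26 members lay above 0 in Kmt2c-KO cells and 11 of 26 in double-KO cells.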
